A study of Homo sapiens with 12 samples.

How the data were processed

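RNA from HepG2 cells was sequenced in 12 libraries: siNC and siCPSF6, each at 0, 3 and 6 h in actinomycin D, with 2 biological replicates per group. Per the labels' protocols, cells were transfected 48 h earlier, ERCC spike-in RNA was added to 5 µg of total RNA, and mRNA libraries were made with a directional kit. Spike-in scaling therefore sets values per mass of total RNA, most of which is ribosomal, and not per cell. Per the submitters' processing notes the tools were STAR and RSEM and the build hg38; their versions, the gene annotation and whether reads were counted by strand are not given in the sources used here.

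The deposited normalized counts are a score: gene-level counts that the authors scaled to an equal upper quartile and rounded to whole numbers, so that they are not raw counts. The upper quartile over all 22235 entries was 660.5 or 661 in each library. Of these entries 87 were spike-ins and 22148 genes. Whole numbers are missing at regular steps where a library was scaled up, and the spacing of attainable values gave scaling factors of 0.7036 to 1.3984 and a depth of 21800000 to 30300000 reads per library; the method returned 5 simulated factors to within 0.0002. The spike-ins took 1.125% to 1.429% of the normalized counts of a library. A second deposited table holds TPM, which the authors computed over the same entries and which has the same total in each library; it was used as an alternative and for the apparent transcript length (below). Because of this unit, tests made for raw counts were not run.

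Group means were compared with limma 3.58.1 (R 4.3.3; empirical Bayes with trend and robust settings) on log2(normalized count + 1), in 1 fit of all 12 libraries with 6 group means and 6 residual degrees of freedom. Genes with a mean of at least 20 were tested (12939), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The comparisons were siCPSF6 against siNC at 0 h and averaged over the 3 times, 6 h against 0 h in each arm, and the difference of that change between the arms. Lists of genes were tested with camera (correlation preset at 0.01, and estimated per list as an alternative) on the same fit, adjusted over the 21 lists within a comparison. A second list test, fry, was set in advance and run as well. In the average it passed the unfolded protein list (fry adjusted p = 7.6e-06), which camera did not. For the difference between the arms it did not pass the ribosomal list (fry adjusted p = 0.059), which camera did. Its other results are not reported here. Both the directions and the counts of members are from limma.

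Before the data were examined, the groups, tests, gene lists, alternatives and the rule for named genes were set. The rule takes CPSF6, NQO1, MYC and ALB, then for each comparison the 10 genes with the largest rise and the 10 with the largest fall among those that passed, with a mean of at least 100 and a symbol that is not a clone name, and up to 4 members with the smallest p of each list; some genes that the rule takes are not reported here. The lists covered 3′ end processing, targets of cleavage factor Im, immediate early and AU-rich mRNAs, KRAB zinc fingers, p53, NRF2, interferon and hypoxia genes, glycolysis, the pentose phosphate pathway, the respiratory chain, mitochondrially encoded mRNAs, ribosomal proteins, plasma proteins, cholesterol and fatty acid metabolism, the cell cycle, histones, snoRNA hosts and NMD-sensitive RNAs, the unfolded protein and integrated stress response, and markers of stromal, endothelial and immune cells. Of these 14 markers 10 passed the filter on the mean, so their presence alone does not show other cells.

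The alternatives set in advance were pseudocounts of 0.1 and 10, no filter or a mean of at least 100, median-ratio and spike-in scaling, the TPM table (mean of at least 1), limma without trend or robust settings, the replicate number as a term, only the groups of a comparison, an estimated correlation for camera, and each library left out in turn. A fit without the 6 h libraries, and counts of gains from 3 to 6 h against single 3 h libraries, were added after seeing the data. Replicate pairs correlated at 0.9919 to 0.994 and differed by more than counting noise (chi-square per degree of freedom 6.7 to 12.01), so no library was a copy of another. Deviations of same-numbered libraries from their group means correlated at 0.11 to 0.24 over the 15 pairs of groups, so the replicate numbers were taken to pair the libraries; this pairing rests on the values, as the labels name no shared day or batch, and the main comparisons have no block.

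Gene symbols were known for 22069 of 22148 identifiers, and 21694 identifiers, with coordinates on hg38, matched GENCODE release 29, which may not be the annotation the authors used. A gene that overlaps another on its strand or, as strand use is not stated, on the opposite strand is named as uncertain.

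The apparent transcript length of a gene was taken as normalized count divided by TPM, log2, relative to the median of the spike-ins of each library, for 8215 genes with a mean of at least 300, and tested with limma in the same design; this measure and the 3′ UTR words below were added after the data were seen. The genes named for it are the 8 shortest and 5 longest among calls with a mean of at least 1000, and NEAT1, NUDT21, CPSF6 and NQO1, a choice made after the values were seen. It follows the mix of transcripts that the authors' quantification assigned. For 3′ UTR words, all 16235 words of 7 bases found in the 3′ UTRs of at least 40 of 10022 genes were ranked by the shift of the genes that carry them, for several comparisons, so that the words named were chosen from a search; 6-base and 8-base words were looked at as well. Shifts are differences of means after a regression on length and GC content, with their SE and 10000 permutations of genes.

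Each procedure was tested on simulated data. With 50 genes changed per size, limma recovered 28%, 78%, 98% and 100% of log2 changes of 0.3, 0.5, 1 and 2 at 0 h, with 3 false calls among 12904 genes. For the average over the times it recovered 72% at 0.3 and 100% at 0.5 (4 false calls among 12897 genes), for 6 h against 0 h 36% and 71.4% in siNC (3 among 12749) and 26% and 73.5% in siCPSF6 (7 among 12761), and for the difference between the arms 8% and 54% (5 among 12906). These limma simulations gave every gene the same dispersion (0.00269) and drew the libraries independently. Real genes differed in spread and same-numbered libraries were correlated, so the rates may be too favourable for these data. The apparent length test recovered 36%, 64%, 78% and 96% of changes of 0.1, 0.2, 0.4 and 0.8 among 8215 genes, with 6 false calls. The word search ranked all 10 simulated words first, each planted as a log2 shift of 0.15 on shuffled genes. Smaller shifts were not simulated. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.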

Results

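HepG2 is a human liver cancer line often used as a model of hepatocytes. Cells were transfected with siRNAs against CPSF6 (siCPSF6) or with a control siRNA (siNC) and cultured for 48 h. Actinomycin D, which blocks transcription, was then added at 5 µg/ml, and cells were collected after 0, 3 and 6 h. CPSF6 encodes the large subunit of cleavage factor Im, which binds nascent RNA and takes part in the choice of the 3′ end. The design asks how CPSF6 silencing changes RNA levels and the loss of RNA once transcription has stopped. There were 6 groups of 2 biological replicates, 12 libraries in all. The deposited normalized counts summed to between 19133288 and 33352246 per library, and the steps between attainable values gave a depth of 21800000 to 30300000 reads. Values below are log2 differences of group means of log2(normalized count + 1), with the standard error (SE) and an adjusted p from limma with Benjamini-Hochberg adjustment over 12939 genes. A fold on this scale understates the change of genes with low counts.

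Time in actinomycin D separated the libraries along the first component (59.8% of the variance) and the siRNA along the second (24.3%). On the third component (6.3%) the siNC libraries stood at -25.9 and -27.2 after 3 h and at 29.3 and 26.4 after 6 h. The siCPSF6 libraries stood at -11.3 and -12.4 after 3 h and at 0.6 and -0.8 after 6 h. The step from 3 to 6 h along this component was larger in siNC than in siCPSF6.

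**Figure D1:**
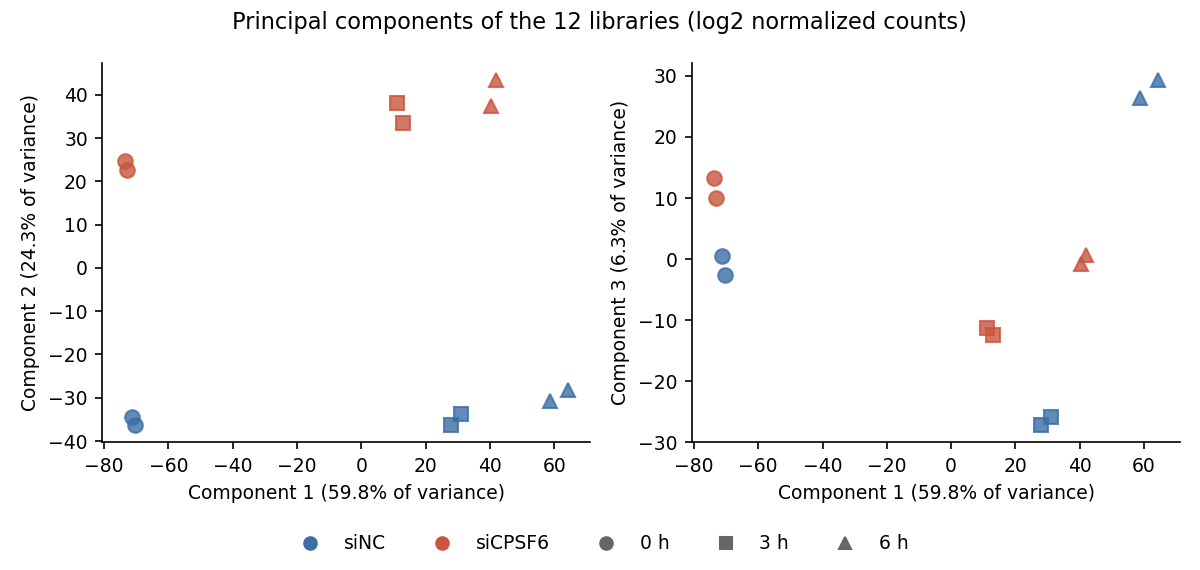
Scores of the 12 libraries on components 1 and 2 (left) and 1 and 3 (right), coloured by siRNA and shaped by hours in actinomycin D. The siNC libraries of 6 h stand at 29.3 and 26.4 on component 3, and those of 3 h at -25.9 and -27.2.

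CPSF6 itself (ENSG00000111605.18; chromosome 12, 69239537 to 69274358 of hg38) was lower in every siCPSF6 library than in any siNC library. Its normalized count at 0 h was 2114.5 ± 46 (SD, n = 2) in siNC and 743 ± 35.4 (SD, n = 2) in siCPSF6. After 6 h it was 3456 ± 18.4 and 771 ± 55.2 (SD, n = 2 each), while its change from 0 h was -0.25 in siNC and -0.81 in siCPSF6 on the log2 scale when scaled to the spike-in RNA. Averaged over the 3 times, CPSF6 fell to 0.258 of the siNC level (log2 -1.95, SE 0.05, adjusted p = 2.8e-13). NQO1 (ENSG00000181019.13), a quinone reductase controlled by NRF2 and named in advance because a link to CPSF6 has been reported, fell by 0.40 on the log2 scale (SE 0.04, adjusted p = 1.8e-07). Its apparent length (normalized count over TPM, log2) changed by -0.19 (SE 0.01) in the same average. As normalized counts also follow transcript length, part of this fall can reflect length. MYC, which encodes a growth-promoting transcription factor, rose by 0.72 (SE 0.11, adjusted p = 9.5e-05). ALB, the albumin gene (mean count 218000), had a difference of 0.07 that did not pass (SE 0.04, adjusted p = 0.15), but passed with the replicate block (0.07) and with median-ratio scaling (0.11). CPSF6 and NQO1 each overlap 1 annotated gene on the opposite strand.

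**Figure D2:**
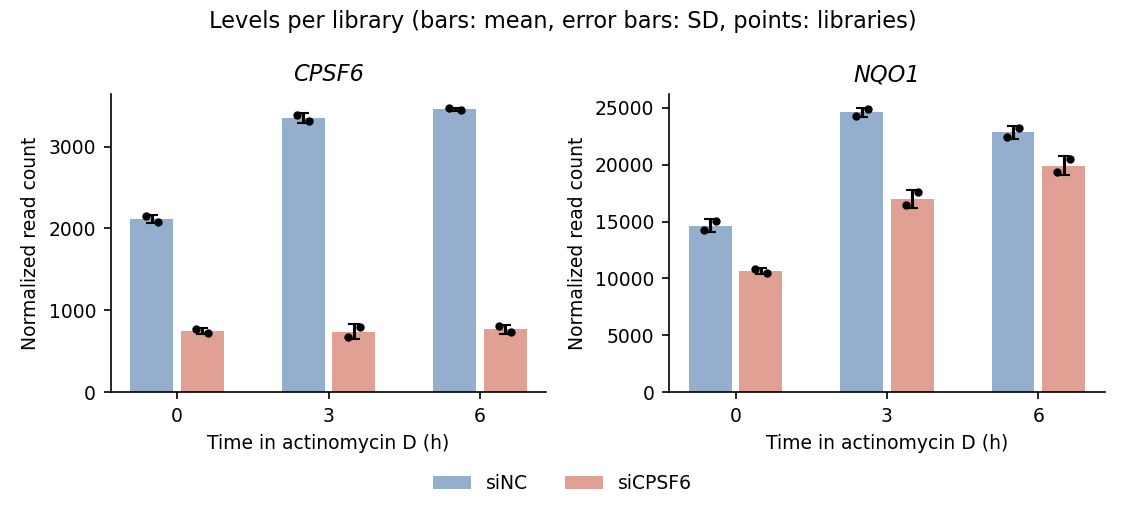
Normalized read counts of CPSF6 and NQO1 by hours in actinomycin D; bars are means of 2 libraries, error bars the SD, and points single libraries. The group means of CPSF6 lie between 737.5 and 771 in siCPSF6 and between 2114.5 and 3456 in siNC.

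The comparison at 0 h asks how silencing of CPSF6 changed RNA levels while transcription was running. MMP2, a gelatinase that degrades matrix, rose 10.8-fold (log2 3.43, SE 0.13, adjusted p = 7.7e-10). VCAN, a matrix proteoglycan, rose by 2.48 and IGFBP4, which binds insulin-like growth factors, by 2.19 (SE 0.14 and 0.09). F7, coagulation factor VII, fell to 0.178 of its siNC level (log2 -2.49, SE 0.17, adjusted p = 7.7e-08). NEAT1, the noncoding RNA that scaffolds paraspeckles, fell to 0.234 (log2 -2.10, SE 0.24, adjusted p = 0.00038).

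At 0 h, 5557 of 12939 genes differed, 2825 higher and 2732 lower in siCPSF6. Scaled to the spike-in RNA, 3706 differed, 1155 higher (31.2%, against 50.8% as deposited) and 2551 lower, and the median over all genes moved from 0.002 to -0.13. Further genes that rose at 0 h were PLA2G3 (a secreted phospholipase, 2.99), APOA4 (an apolipoprotein, 2.41), RBM15 (a subunit of the RNA methyltransferase complex, 2.39), HABP4 (2.28) and KREMEN2 (a receptor in Wnt signalling, 2.13). UGT1A1, which conjugates bilirubin, had a value of 3.25 (SE 0.30), but overlaps 8 other annotated genes on its strand. Genes that fell were PIGZ (a mannosyltransferase of membrane anchors, -2.54), the noncoding LINC00641 (-2.32), NHERF2 (a scaffold protein, -2.22), PAGR1 (-2.11), NGEF (a guanine nucleotide exchange factor, -2.08) and NKAP (-2.06). ACSL3P1, a processed pseudogene that can share reads with its parent, had -2.76 (SE 0.21) and PTGDR2, a prostaglandin D2 receptor that overlaps other genes, -2.26 (SE 0.34). NEAT1, PAGR1 and MMP2 overlap another gene on their own strand, and VCAN, APOA4, RBM15, HABP4, KREMEN2, NGEF and NKAP overlap a gene on the opposite strand, so part of their counts is uncertain.

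The list of unfolded protein and integrated stress response genes was higher in siCPSF6 at 0 h, with 12 of 24 members higher, 5 lower and 7 not passing the test (camera adjusted p = 0.042; 12 higher and 5 lower when adjusted over the list alone). Its adjusted p was 0.68 with an estimated correlation, and 0.063 without the 6 h libraries, a comparison added after the data were seen. The call was also lost, at adjusted p = 0.051 to 0.054, without siNC 0 h replicate 2 and without any 1 of the libraries of siNC 6 h, siCPSF6 3 h or siCPSF6 6 h. Among the 12 higher members of this list, SDF2L1 rose by 1.26 (SE 0.07), CALR (calreticulin) by 1.25 (SE 0.06), MANF by 1.06 (SE 0.07) and HSPA5 by 0.90 (SE 0.08). The other 20 lists did not pass camera at 0 h as deposited with all libraries and no block. With TPM the immediate early (adjusted p = 0.049) and respiratory chain lists (0.0078) did. Without siNC 0 h replicate 1 the glycolysis list passed (0.024), and without siCPSF6 0 h replicate 2 the ribosomal (0.0079), glycolysis (0.031), immediate early (0.048) and cell cycle lists (0.048). Of 22 genes for 3′ end processing, 3 were higher and 6 lower, also when adjusted over the list alone (camera adjusted p = 0.57). NUDT21, the small subunit that pairs with CPSF6 in cleavage factor Im, fell by 0.32 (SE 0.06, adjusted p = 0.00086), and WDR33, which binds the polyadenylation signal, fell by 0.44 (SE 0.09, adjusted p = 0.00099). Normalized counts also follow transcript length, and the apparent length of NUDT21 (normalized count over TPM) changed by -1.48 at 0 h. This is more than its count fell, so the count does not show that NUDT21 molecules were fewer. Of 25 NRF2 targets, 7 were higher and 9 lower, in both adjustments (camera adjusted p = 0.52). SLC7A11, the cystine transporter, rose by 1.09 (SE 0.10), whereas AKR1B10, an aldo-keto reductase, fell by 1.61 (SE 0.16).

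Averaged over 0, 3 and 6 h, nuclear mRNAs of the respiratory chain and mRNAs of ribosomal proteins were lower in siCPSF6, though at 0 h their list medians were -0.03 and 0.05 as deposited (-0.09 and -0.05 with TPM, -0.17 and -0.08 with spike-in scaling). Of 59 nuclear genes of the respiratory chain 42 fell and 17 did not pass (42 also when adjusted over the list alone), with a list median of -0.19 (camera adjusted p = 3.8e-06; adjusted p = 0.58 with an estimated correlation). NDUFS1 and NDUFB9, subunits of complex I, fell (-1.10 and -1.06, SE 0.05 each). Of 74 cytosolic ribosomal protein genes 48 fell, 1 rose and 25 did not pass, 46 and 1 when adjusted over the list alone (camera adjusted p = 0.00015; adjusted p = 0.92 with an estimated correlation). RPL27 (-0.52, SE 0.05) and RPL22 (-0.44, SE 0.04) were among those that fell. Of 13 mitochondrially encoded mRNAs 9 rose and 4 did not pass, in both adjustments (median 0.14), and with spike-in scaling 3 rose (median 0.09). The list had camera adjusted p = 0.072 (adjusted p = 0.58 with an estimated correlation), and passed with the replicate block (0.033), with TPM (0.042) and without siNC 3 h replicate 1 (0.049). At 0 h, where its median was 0.19, or 0.05 with spike-in scaling, it had 0.071 (adjusted p = 0.89 with an estimated correlation), and passed with the block (0.021) and without siNC 0 h replicate 1 (0.024) or siCPSF6 0 h replicate 1 (0.037).

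Genes of cholesterol synthesis and short-lived mRNAs were higher in this average as deposited, and both lists had a camera adjusted p of 0.054 with the TPM table. Of 22 cholesterol genes 13 rose, 6 fell and 3 did not pass, in both adjustments (median 0.29, camera adjusted p = 0.031; adjusted p = 0.58 with an estimated correlation). MSMO1 rose by 0.89 (SE 0.04) and FDFT1, squalene synthase, by 0.69 (SE 0.03). Of 36 immediate early and AU-rich mRNAs 19 rose, 3 fell and 14 did not pass, in both adjustments (median 0.34, camera adjusted p = 0.031; adjusted p = 0.58 with an estimated correlation). RHOB, a small GTPase, rose by 1.05 (SE 0.05) and ZFP36L1, which binds AU-rich elements, by 0.98 (SE 0.05), while JUND fell by 1.71 (SE 0.10). Of 14 genes known for 3′ UTR changes with cleavage factor Im 8 rose, 3 fell and 3 did not pass, in both adjustments (camera adjusted p = 0.2). IGF1R, a growth factor receptor gene, rose by 1.04 (SE 0.06), while CCND1 (cyclin D1) fell by 0.58 (SE 0.04). The unfolded protein list did not pass in the average (median 0.40, camera adjusted p = 0.1; adjusted p = 0.58 with an estimated correlation), but passed, upward, without the 6 h libraries (0.034).

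In the average 9034 genes differed, 4456 higher and 4578 lower, and 4665 of the 5557 genes called at 0 h (83.9%) had the same sign at 3 h and 6 h. Besides genes named above, the splicing regulator gene HNRNPLL (-2.21, SE 0.07), SMIM14 (-2.20, SE 0.08) and PIP5K1B (-2.16, SE 0.13) fell. MAPK8IP2 (a scaffold of JNK signalling) rose by 2.25 (SE 0.09), SCN1A (a sodium channel) by 2.23 (SE 0.13), NOTCH3 by 2.14 (SE 0.14) and FRMD3 by 2.09 (SE 0.13). SMIM11 had -2.20 with an SE of 0.59 (adjusted p = 0.014). PIP5K1B and SCN1A overlap a gene on the opposite strand. Of 10 markers of stromal, endothelial and immune cells 3 were higher and 4 lower, in both adjustments (camera adjusted p = 0.92), with a median of -0.01 and a mean of 0.12. CD14 rose by 1.64 (SE 0.11) and the smooth muscle actin gene ACTA2 fell by 1.05 (SE 0.09).

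The comparisons of 6 h with 0 h ask which RNAs were lost once transcription was blocked. MYC fell in siNC (-4.42, SE 0.19, adjusted p = 4.9e-10) and in siCPSF6 (-4.74, SE 0.19, adjusted p = 6.6e-10). NFKBIA, the inhibitor of NF-κB, fell (-4.88 and -5.26, SE 0.28 each), as did XBP1, a transcription factor of the unfolded protein response (-4.17 and -4.68, SE 0.08 each). ALB stood 1.02 higher in siNC (SE 0.08) and 1.13 higher in siCPSF6 (SE 0.08) against the upper quartile of each library, but 0.06 and 0.27 higher, not passing the test, when scaled to the spike-in RNA. The mitochondrial ribosomal RNA MT-RNR1 rose by 3.26 and 3.37 (SE 0.09 each), and by 2.29 and 2.51 when scaled to the spike-in RNA. As these were mRNA libraries, its counts need not follow the whole level of this ribosomal RNA.

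Each time course is relative to a scale, since the authors set the upper quartile of each library to the same value. As deposited 10265 genes changed in siNC, 6292 higher (61.3%) and 3973 lower, and 10015 in siCPSF6, 6439 higher (64.3%) and 3576 lower. Scaled to the spike-in RNA, which was added per 5 µg of total RNA and not per cell, 8794 changed in siNC (1325 higher, 15.1%, and 7469 lower) and 7536 in siCPSF6 (754 higher, 10%, and 6782 lower). With median-ratio scaling 50.7% (siNC) and 51.4% (siCPSF6) of the calls were higher, and with TPM 23.5% and 22.7%. The median over all genes moved from 0.31 in siNC to -0.65 with spike-in scaling, -0.43 with TPM and 0.03 with median-ratio scaling, and in siCPSF6 from 0.35 to -0.50, -0.32 and 0.07. The spike-in values themselves rose by 0.96 (siNC) and 0.86 (siCPSF6) from 0 to 6 h.

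The genes lowest after 6 h in siNC were MT-ND6 (the light-strand gene of complex I, -7.40), HAMP (hepcidin, the iron hormone, -6.11), ID2 (an inhibitor of helix-loop-helix factors, -5.90), CEBPA (a hepatocyte transcription factor, -5.23), ELF3 (-5.22), DDIT4 (an inhibitor of mTOR signalling, -5.21), BAMBI (-5.14) and HPS6 (-4.80). In siCPSF6 they were BAMBI (-6.61), MT-ND6 (-6.58), TRIB1 (-4.85), MYC, XBP1, DDIT4 (-4.66), ID2 (-4.65) and CCDC71 (-4.58), with NFKBIA in both arms. CDC42EP2 had -5.92 and -6.30 with an SE of 1.74. Its call was lost in siNC without 0 h replicate 1 (-5.84) or 2 (-6.00) or 6 h replicate 2 (-4.07), and in siCPSF6 without 0 h replicate 1 (-6.25) or 6 h replicate 2 (-3.89). It was also lost in siNC with a pseudocount of 0.1 (-7.63), and in siCPSF6 with only the groups compared. Among the highest in siNC were LCN15 (a lipocalin, 3.47), CAPN12 (2.93), SERPINI1 (neuroserpin, 2.82), MMP23B (2.80), NT5E (which makes adenosine, 2.78), TPM2 (tropomyosin, 2.77), BPIFB2 (2.67), PODXL2 (2.66) and UGT1A1 (3.88). In siCPSF6 they were NEAT1 (2.85), EME2 (2.31), SLC22A18 (2.26) and a group whose reads cannot be assigned with certainty: SULT1A4, which has a near-identical copy (4.19, SE 1.34), the pseudogenes SMG1P4 (2.51) and SMG1P3 (2.43), the readthrough genes STX16-NPEPL1 (2.42) and TEN1-CDK3 (2.26), and PRSS53 (2.42). SULT1A4 lost its call without siCPSF6 0 h replicate 2 (2.87), without 6 h replicate 1 (4.12) or 2 (4.26), with spike-in scaling (3.34), with only the groups compared, and at 3 h (0.10). Of the genes highest in siNC, LCN15, CAPN12, SERPINI1, MMP23B and NT5E stood at 1.40, 2.20, 0.71, 1.90 and 0.60 at 3 h. TPM2, BPIFB2, PODXL2 and UGT1A1 stood at 1.97, 1.33, 1.01 and 0.86. Part of each rise therefore came after 3 h and rests on the siNC libraries of 6 h. ELF3 and CDC42EP2 overlap a gene on their strand, and ID2, CEBPA, DDIT4, CAPN12, MMP23B, EME2 and SLC22A18 a gene on the opposite strand.

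Of the 36 immediate early and AU-rich mRNAs, 34 fell in siNC and 36 in siCPSF6, and the counts were equal when adjusted over the list alone. The list medians were -2.76 and -2.85 (camera adjusted p = 2.2e-13 and 1.9e-16). These were the only list calls that held with an estimated correlation (adjusted p = 0.012 in siNC and adjusted p = 0.0063 in siCPSF6, each with an estimated correlation). RHOB fell (-3.95 and -3.73, SE 0.09 each), as did ZFP36L2, which promotes mRNA decay (-3.95 and -3.31, SE 0.11 each).

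Of 85 KRAB zinc finger genes, which encode transcriptional repressors, 49 fell and 13 rose in siNC and 46 fell and 15 rose in siCPSF6, in both adjustments (camera adjusted p = 0.00018 and 3.8e-05; adjusted p = 0.074 and 0.052 with an estimated correlation). ZNF689 fell (-3.75 and -2.79, SE 0.18 each). Of 28 p53 targets 15 fell and 7 rose in siNC and 13 fell and 8 rose in siCPSF6, in both adjustments (camera adjusted p = 0.0051 and 0.022; adjusted p = 0.27 and 0.3 with an estimated correlation). CDKN1A (p21) fell (-2.08 and -2.49, SE 0.11 each). Of 39 cell cycle genes 20 fell and 11 rose in siNC and 18 fell and 13 rose in siCPSF6, in both adjustments (camera adjusted p = 0.017 in each arm; adjusted p = 0.63 and 0.66 with an estimated correlation). AURKA, a mitotic kinase, fell (-2.77 and -2.31, SE 0.08 each). The siNC call of this list had adjusted p = 0.053 without siNC 6 h replicate 1. Of 13 mitochondrially encoded mRNAs 9 fell in each arm and 1 (siNC) or 3 (siCPSF6) rose, in both adjustments (camera adjusted p = 0.0027 and 0.0019; adjusted p = 0.33 and 0.3 with an estimated correlation). MT-ND2 fell (-3.10 and -2.87, SE 0.06 each) as did MT-CYB (-2.51 and -2.02, SE 0.07 each). At 3 h, with the 6 h libraries left out, neither the cell cycle list (adjusted p = 0.62 and 0.46) nor the mitochondrial list (adjusted p = 0.42 and 0.095) passed. With spike-in scaling the members that fell in siNC and siCPSF6 were 73 and 70 KRAB zinc finger genes, with 1 that rose in each arm, 22 and 20 p53 targets, 31 and 32 cell cycle genes and 12 and 13 mitochondrially encoded mRNAs. The cell cycle medians were -0.24 and -0.04 as deposited and -1.20 and -0.90 with spike-in scaling.

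Lists of housekeeping and liver genes rose relative to the upper quartile. All 74 ribosomal protein genes rose in both arms, with medians of 1.44 in siNC and 1.12 in siCPSF6 (camera adjusted p = 1.3e-16 and 1.5e-15; adjusted p = 0.4 and 0.41 with an estimated correlation), and with spike-in scaling 61 and 25 of them rose (medians 0.48 and 0.26). All 59 respiratory chain genes rose in both arms, with medians of 1.27 and 0.93 (camera adjusted p = 5.7e-13 and 6e-11; adjusted p = 0.29 and 0.3 with an estimated correlation), whereas with spike-in scaling 24 rose and 3 fell in siNC (median 0.31), and 7 rose and 6 fell in siCPSF6 (median 0.07). Of 32 genes for secreted plasma proteins 30 rose in each arm, and 1 fell in siNC (median 1.23 in each arm, camera adjusted p = 1.8e-05 and 3.6e-07; adjusted p = 0.4 and 0.3 with an estimated correlation). TTR (transthyretin) rose by 2.29 (SE 0.09) and FGG (fibrinogen) by 2.25 (SE 0.09) in siNC. All 12 genes of the pentose phosphate pathway and NADPH supply rose in both arms (medians 1.14 and 0.94, camera adjusted p = 0.00064 and 0.0011; adjusted p = 0.074 and 0.052 with an estimated correlation), and IDH2 rose by 1.51 and 1.18 (SE 0.07 each). Of 21 glycolysis genes 15 rose in each arm and 2 (siNC) or 1 (siCPSF6) fell (camera adjusted p = 0.017 in each; adjusted p = 0.63 and 0.66 with an estimated correlation), and GAPDH rose by 1.36 and 1.25 (SE 0.08 each). Of 21 genes of fatty acid synthesis and oxidation 18 and 20 rose (camera adjusted p = 0.00064 and 2e-04; adjusted p = 0.074 and 0.052 with an estimated correlation), but the median flipped from 0.78 and 0.75 to -0.19 and -0.11 when scaled to the spike-in RNA. With spike-in scaling 14 plasma protein genes rose and 5 fell in siNC and 20 rose in siCPSF6 (medians 0.26 and 0.37). On that scale 4 pentose phosphate and NADPH genes rose and 2 fell in siNC and 2 fell in siCPSF6 (medians 0.18 and 0.08), and 8 glycolysis genes rose and 6 fell in siNC, while 2 rose and 4 fell in siCPSF6. For the 6 lists of this paragraph the counts as deposited were the same when adjusted over the list alone.

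The other lists did not pass camera in either time course as deposited with all libraries and no block. The unfolded protein list had a median of 0.90 in siNC and 0.60 in siCPSF6 but means of -0.13 and -0.44, since 10 of its 24 members fell in each arm (camera adjusted p = 0.65, upward, and 0.84, downward), and with spike-in scaling the medians turned to -0.06 and -0.26. Median and mean also differed in sign for hypoxia genes (0.49 and -0.43 in siNC, 0.53 and -0.31 in siCPSF6), for targets of cleavage factor Im (0.04 and -0.23, 0.11 and -0.05), for cholesterol genes in siNC (0.05 and -0.01) and for snoRNA hosts in siCPSF6 (0.11 and -0.05), and each of these medians turned with spike-in scaling: to -0.47 and -0.33 for hypoxia genes, -0.92 and -0.75 for targets of cleavage factor Im, -0.91 for cholesterol genes and -0.75 for snoRNA hosts. The markers of other cell types had camera adjusted p = 0.053 in siNC, where 9 of 10 rose in both adjustments, and 0.13 in siCPSF6, where 9 of 10 rose (adjusted p = 0.27 and 0.3 with an estimated correlation). With spike-in scaling 2 and 1 of them rose, and the medians were 0.41 and 0.27 against 1.36 and 1.12 as deposited. This list passed in both arms with the replicate block (adjusted p = 0.019 and 0.045) and with TPM (0.0032 and 0.012), and in siNC without either siNC 3 h library (0.041) or any 1 of the libraries of siCPSF6 0 h and 6 h (0.047). CD68 rose by 1.56 and 1.47 (SE 0.08 each). Cholesterol genes had adjusted p = 0.58 and 0.45, NRF2 targets 0.37 and 0.13, genes for 3′ end processing 0.31 and 0.12 (0.031 in siCPSF6 with TPM), targets of cleavage factor Im 0.31 and 0.63, snoRNA host and NMD-sensitive RNAs 0.37 and 0.79, interferon-stimulated genes 0.99 and 0.82, hypoxia genes 0.37 in both arms and replication-dependent histones 0.37 and 0.39.

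**Figure D3:**
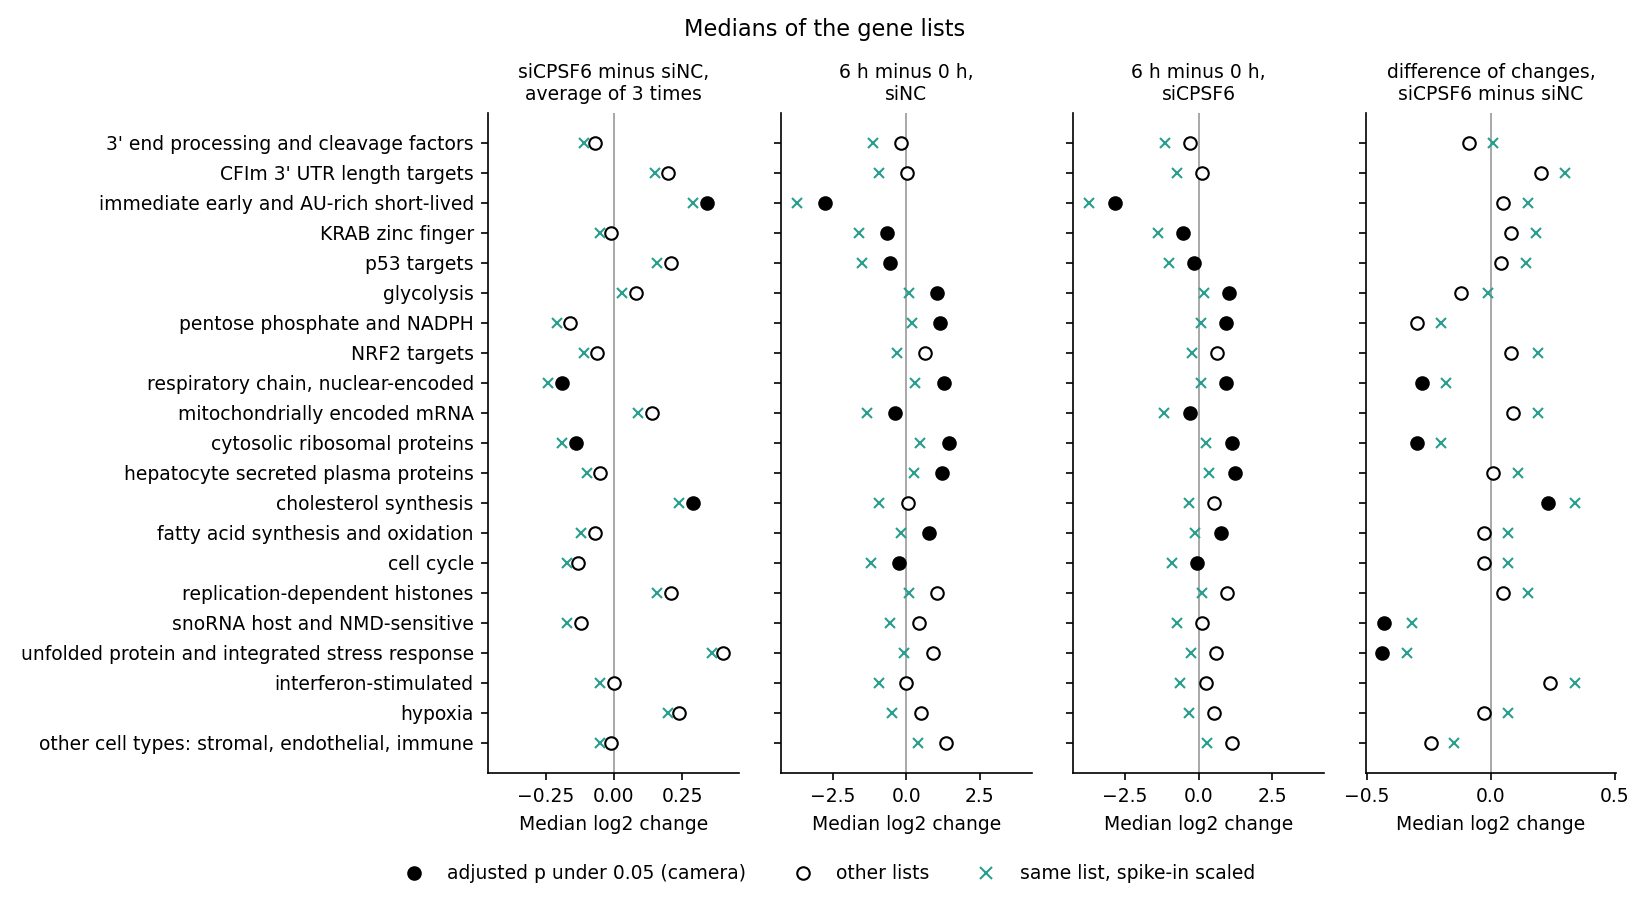
Median log2 difference of each of 21 gene lists for the siRNA average, for 6 h against 0 h in each arm and for the difference between arms; filled circles have a camera adjusted p under 0.05, open circles do not, and crosses are spike-in scaled. The fatty acid list stands at 0.78 in siNC as deposited and flips to -0.19 when spike-in scaled.

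The difference of the 6 h change between the arms asks whether silencing of CPSF6 altered the loss of RNA. FAM120A, which encodes an RNA-binding protein, went from 0.49 at 3 h to -1.60 at 6 h in siNC, relative to 0 h, and from 0.53 to 0.83 in siCPSF6 (difference 2.44, SE 0.13, adjusted p = 2.9e-08). GM2A, which encodes a lysosomal lipid-transfer protein, went from 0.68 to -1.13 in siNC and from 0.69 to 1.14 in siCPSF6 (difference 2.27, SE 0.13, adjusted p = 1e-07). SLC7A11 went from 0.36 to 2.30 in siNC and from 0.49 to 0.64 in siCPSF6 (difference -1.67, SE 0.14, adjusted p = 1.7e-06). HABP4 went from 0.20 to 2.21 in siNC and from 0.32 to 0.44 in siCPSF6 (difference -1.77, SE 0.14, adjusted p = 1.4e-06). RBM15 differed already at 3 h, by -1.80 (adjusted p = 0.00015), and by -1.92 at 6 h (SE 0.17, adjusted p = 3.4e-06).

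**Figure D4:**
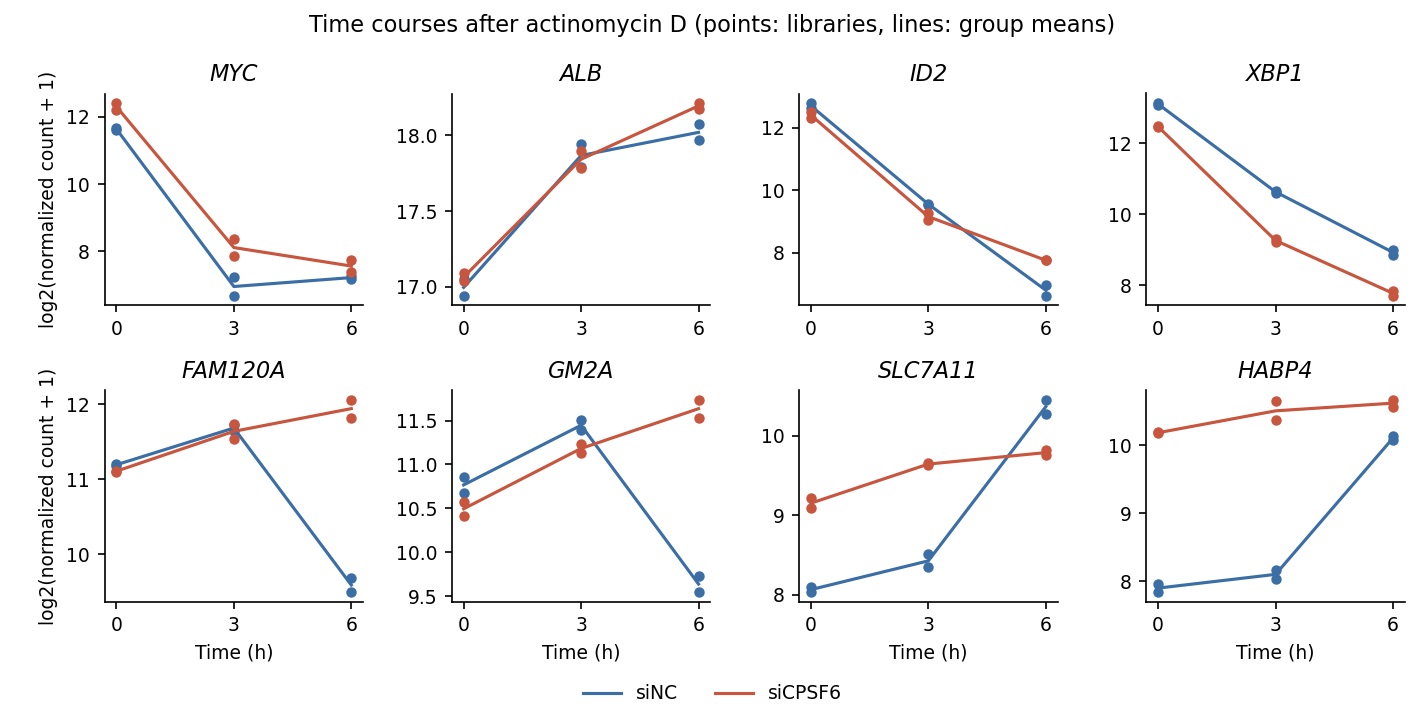
Log2(normalized count + 1) against hours in actinomycin D for 8 genes; points are single libraries and lines join group means, in siNC and siCPSF6. FAM120A and GM2A end at -1.60 and -1.13 relative to 0 h in siNC, and at 0.83 and 1.14 in siCPSF6.

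In total 3153 genes differed in their 6 h change, 1547 higher and 1606 lower in siCPSF6 than in siNC. With spike-in scaling 1130 did, 892 higher (78.9%, against 49.1% as deposited) and 238 lower, and with TPM 1553, 1000 higher (64.4%) and 553 lower. Without the 6 h libraries 672 genes differed in their 3 h change, 463 higher and 209 lower, whereas the fit of all 12 libraries gave 387 for the same 3 h difference, 292 higher and 95 lower. Leaving out siCPSF6 0 h replicate 1 gave 2017 genes, 958 of them lower, and leaving out siNC 0 h replicate 2 gave 1027 lower. Among 6616 genes with a mean count of at least 500, scaled to the spike-in RNA, 360 gained more than 0.5 from 3 to 6 h in siNC and 4 did in siCPSF6, while 1508 and 1162 lost more than 0.5. The spike-in level of the siCPSF6 3 h libraries differed by 0.37, and against single 3 h libraries the counts of gains were 425 (replicate 1) and 331 (replicate 2) in siNC, and 21 and 2 in siCPSF6.

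SLC6A12 (a betaine transporter, 3.58, SE 0.23), PTGDR2 (3.11, SE 0.48), BMT2 (2.44, SE 0.25), TRIM47 (a ubiquitin ligase, 2.43, SE 0.21), ITGAL (an integrin, 2.31, SE 0.45), TRPV4 (a cation channel, 2.26, SE 0.26), PHLDA3 (a p53 target, 2.26, SE 0.24) and DGCR2 (2.26, SE 0.12) had a higher change in siCPSF6. UGT1A1 (-2.82, SE 0.43), LCN15 (-2.03, SE 0.49), MT1E (a metallothionein with close paralogs, -1.95, SE 0.19), BCL7B (a chromatin remodelling subunit, -1.85, SE 0.20), LONRF3 (-1.84, SE 0.24), MKKS (-1.76, SE 0.36) and TESC (-1.68, SE 0.30) had a lower one. Of the 20 genes with the largest differences, RBM15, TRIM47 (0.93) and DGCR2 (0.49) also passed without the 6 h libraries, and the other 17 did not. Over all 3153 calls, 2515 (79.8%) had the same sign at 3 h, with a median of 30.5% of the 6 h value. In the fit of all 12 libraries 276 genes were called at both times, 261 with the same sign. Both differences share the 0 h libraries, which favours equal signs. The differences of TRPV4 and PHLDA3 turned at 3 h (-0.18 and -0.28), as did those of SLC7A11 (0.13) and HABP4 (0.12), and BMT2 lost its call with the TPM table (0.75). LCN15 lost its call without siCPSF6 6 h replicate 2 (-1.78) and without siNC 0 h replicate 1 (-2.12) or 2 (-1.95). PTGDR2, MKKS and PHLDA3 overlap a gene on their strand, and SLC6A12, FAM120A, TRIM47, ITGAL, TRPV4, SLC7A11, HABP4 and RBM15 a gene on the opposite strand. CPSF6 differed by -0.66 (SE 0.12, adjusted p = 0.0014; -0.55 and adjusted p = 0.14 with spike-in scaling). NQO1 differed by 0.26 (SE 0.09, adjusted p = 0.049), a call lost when any 1 of the 12 libraries was left out (0.22 to 0.31), with spike-in scaling (0.37, adjusted p = 0.29) or median-ratio scaling (0.25), and, at 0.26, with no filter, without trend and robust settings or with only the groups compared. Its 3 h difference was -0.07. MYC and ALB differed by -0.32 and 0.11 (adjusted p = 0.43 and 0.51), and ALB passed with TPM (0.23).

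Ribosomal and respiratory mRNAs gained less in siCPSF6 than in siNC. Of 74 ribosomal protein genes 39 had a lower change and 35 did not pass (49 lower when adjusted over the list alone), with a median of -0.30 (camera adjusted p = 4.7e-12; adjusted p = 0.67 with an estimated correlation). RPL11 had -0.62 (SE 0.11) and RPS26 -0.68 (SE 0.13). Of 59 respiratory chain genes 24 were lower and 1 higher (33 and 1 when adjusted over the list alone), with a median of -0.28 (camera adjusted p = 1.4e-09; adjusted p = 0.49 with an estimated correlation). With spike-in scaling the medians were -0.20 and -0.18, 1 respiratory gene passed, and the other calls of single members were lost in both lists. Both lists passed without the 6 h libraries at the preset correlation (camera adjusted p = 1.2e-18 and 1.8e-13), with 3 h medians of -0.25 and -0.23. The estimated correlation was not run without the 6 h libraries, for these or the other lists. The 3 h and 6 h differences also share the 0 h libraries.

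Of 23 snoRNA host and NMD-sensitive RNAs 13 were lower and 1 higher (15 and 2 when adjusted over the list alone; camera adjusted p = 0.00094; adjusted p = 0.27 with an estimated correlation; 0.0011 without the 6 h libraries). SNHG5 had -0.84 (SE 0.13) and ATF4, the transcription factor of the integrated stress response, -0.81 (SE 0.11). Of 24 unfolded protein and integrated stress response genes 12 were lower and 2 higher (13 and 2 when adjusted over the list alone; camera adjusted p = 0.0016; adjusted p = 0.27 with an estimated correlation). ASNS, asparagine synthetase, had -1.61 (SE 0.19). This list's median was -0.44 at 6 h and 0.03 at 3 h, and it did not pass without the 6 h libraries (adjusted p = 0.35). Of 22 cholesterol genes 7 were higher and 2 lower (8 and 2 when adjusted over the list alone; camera adjusted p = 0.023; adjusted p = 0.36 with an estimated correlation), led by MSMO1 (1.31, SE 0.10). The list's median was 0.23 at 6 h and 0.03 at 3 h (adjusted p = 0.057 without the 6 h libraries, and 0.065 without siCPSF6 6 h replicate 1). From 3 to 6 h the unfolded protein median went from 0.26 to 0.90 in siNC, whose 6 h libraries stood at 29.3 and 26.4 on the third component, and from 0.44 to 0.60 in siCPSF6, though the 6 h values turned to -0.06 and -0.26 with spike-in scaling. The cholesterol median went from 0.04 to 0.05 in siNC and from 0.34 to 0.53 in siCPSF6, and the 6 h values likewise turned to -0.91 and -0.33. With spike-in scaling 2 snoRNA host and NMD-sensitive RNAs were lower and 1 higher, 4 unfolded protein genes were lower and 2 higher, and 5 cholesterol genes were higher. The 13 mitochondrially encoded mRNAs had a median of 0.09 (camera adjusted p = 0.6; adjusted p = 0.96 with an estimated correlation). Their list passed upward with TPM (0.013, median 0.23) and downward without the 6 h libraries (0.034), with a median of -0.16 at 3 h. Of the 10 markers of other cell types ACTA2 was lower (-0.69, SE 0.21), though not when adjusted over the list alone (camera adjusted p = 0.45).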

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

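The tests of scaling and of another siRNA or culture were chosen only after the results were seen.

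The 6 h change differed between the arms for 3153 genes by the test of the difference itself. Among the named genes the difference, siCPSF6 minus siNC on the log2 scale, was above 0 for SLC6A12 (3.58), PTGDR2 (3.11), BMT2 (2.44), FAM120A (2.44), TRIM47 (2.43), ITGAL (2.31), GM2A (2.27), TRPV4 (2.26), PHLDA3 (2.26), DGCR2 (2.26), ACSL3P1 (2.08), HAMP (1.90), NEAT1 (1.64), CEBPA (1.46), ID2 (1.26), NOTCH3 (1.23), SMG1P3 (0.71), SLC22A18 (0.67) and NQO1 (0.26). It was below 0 for UGT1A1 (-2.82), LCN15 (-2.03), MT1E (-1.95), RBM15 (-1.92), BCL7B (-1.85), LONRF3 (-1.84), HABP4 (-1.77), MKKS (-1.76), TESC (-1.68), SLC7A11 (-1.67), SERPINI1 (-1.66), NT5E (-1.46), PODXL2 (-1.32), VCAN (-1.07), IGFBP4 (-1.01), TPM2 (-0.94), CPSF6 (-0.66) and XBP1 (-0.51). The list medians that differed were -0.28 for the respiratory chain, -0.30 for ribosomal proteins, -0.43 for snoRNA hosts and NMD-sensitive RNAs, -0.44 for the unfolded protein and integrated stress response and 0.23 for cholesterol synthesis, calls that were lost with an estimated correlation (adjusted p = 0.49, 0.67, 0.27, 0.27 and 0.36). The step from 3 to 6 h itself differed between the arms for 1981 genes.

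The step from 3 to 6 h had an SD of 0.76 in siNC and 0.36 in siCPSF6 among the called genes, which were picked for a difference, and of 0.50 and 0.33 among 6616 genes with a mean count of at least 500, spike-in scaled. The authors' scaling cannot be the whole cause, since 1 factor per library moves all genes alike and the differences went both ways. With spike-in scaling 1094 genes passed with the same sign, 862 higher and 232 lower. These counts are no separate test, as rescaling could hardly alter the spread of the differences (SD 0.54 as deposited and 0.53 with spike-in scaling). A candidate explanation for the part that arose after 3 h is that the siNC cells of 6 h had another siRNA or came from another culture: genes with the word TCGGAGA in the 3′ UTR were 0.213 (SE 0.036) and 0.275 (SE 0.046) higher in siCPSF6 than in siNC at 0 and 3 h but 0.053 (SE 0.04) at 6 h, and the difference of their 3 to 6 h change, siCPSF6 minus siNC, was -0.222 (SE 0.037), or -0.143 (SE 0.016) for the word in the coding part. Set singly against the other groups, the siNC libraries of 6 h gained 0.229 and 0.216, and the word was picked from a search of these data, as the highest at 0 h. For the difference of the 3 to 6 h change it ranked only 7 from the lowest. The lowest word there was TGGAGAA (-0.06, SE 0.01, 2238 genes) and the highest CATTTCA (0.064, SE 0.01, 2243 genes), so the step was not particular to TCGGAGA. A change of RNA stability in cells with less CPSF6, which the design is built to show, was not tested apart from this candidate explanation and stays open. The 672 genes called for the 3 h change without the 6 h libraries do not rest on the siNC libraries of 6 h.

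The ratio of the normalized count to TPM, which the comparisons above do not use, gave 1475 genes with a shorter and 236 with a longer apparent transcript in siCPSF6.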

How the results depend on the processing

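The comparison without the 6 h libraries and the counts against single 3 h libraries were chosen after seeing the data, and the other alternatives before. Of the alternatives for the named genes 2618 gave the same call, 57 lost it, 3 gained it and 11 turned the direction; for the lists these were 1605, 48, 27 and 0, with 30 of the losses from the estimated correlation, which left 2 of 32 list calls. The fold of CPSF6 averaged over the times kept its direction and call under every alternative run, at -1.99 to -1.91 when single libraries were left out. The estimate with only the groups of a comparison is the full design for this average and gave no value of its own, and a count model was not run because the values are not raw counts.

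Spike-in scaling moved the calls to 1155 higher at 0 h, to 1325 higher and 7469 lower over 6 h in siNC, to 754 and 6782 in siCPSF6, and to 1130 for the difference of the changes (892 higher and 238 lower). With TPM the corresponding counts were 1996 and 6513 in siNC, 1753 and 5955 in siCPSF6, and 1553 (1000 and 553) for the difference. In the time courses the median gene fell over 6 h on these scales, by -0.65 (siNC) and -0.50 (siCPSF6) with spike-in scaling. With TPM the medians were -0.43 and -0.32. The deposited scale instead holds the upper quartile of each library equal. The cause of the shifts in these counts was not tested. The change of CPSF6 in siCPSF6 turned to -0.23 with median-ratio scaling, -0.81 with spike-in scaling and -1.10 with TPM. In siNC, CPSF6 turned to -0.25 with spike-in scaling, and NQO1 to -0.32 with spike-in scaling and -0.24 with TPM. The turns with spike-in scaling equal the rise of the spike-in values (0.96 in siNC and 0.86 in siCPSF6) taken from the deposited changes; for the others the cause was not tested.

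Without the 6 h libraries the difference of the changes was called for 672 genes (463 and 209), and turned for HABP4 (0.12), SLC7A11 (0.13), TRPV4 (-0.18), PHLDA3 (-0.28) and NQO1 (-0.07), as the time compared is then 3 h. With single libraries left out, where the lone sample of a group is assumed to vary like the others, this count ranged from 2017 (without siCPSF6 0 h replicate 1) to 3134 and its lower calls from 958 to 1603; the counts lay between 3936 (without siNC 0 h replicate 2) and 5804 at 0 h, 8557 and 8919 for the average, 9528 and 10283 in siNC and 9155 and 10133 in siCPSF6, and list calls between 30 (without siNC 6 h replicate 1) and 37. The cause was not tested.

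With the replicate block the counts were 6549 at 0 h, 9630 for the average, 10588 and 10437 over 6 h in siNC and siCPSF6, 4395 for the difference and 36 list calls, and CPSF6 had -1.95. Among the named genes and lists the block added the call of ALB in the average and 4 list calls, given with those results, and changed no other call.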

Other observations

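The tests of fragment size, uneven coverage, base composition, seed pairing and of length against stability were chosen only after the results were seen; those of an earlier 3′ end and of other splits of the samples were set before their results.

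Transcripts appeared shorter in siCPSF6 for 1475 of 8215 genes and longer for 236, averaged over the times, by limma on the ratio of normalized count to TPM. MBNL3, which encodes a splicing regulator, fell to 0.214 of its apparent length in siNC (log2 -2.23, SE 0.04, adjusted p = 1.5e-07). NUDT21, the partner of CPSF6 in cleavage factor Im, had -1.43 (SE 0.05), the glycosyltransferase gene MGAT4A -1.35 (SE 0.05), the mitochondrial carrier gene SFXN1 -1.33 (SE 0.04), AGO2, which acts in RNA silencing, -1.31 (SE 0.11), LEPROTL1 -1.29 (SE 0.07), GOLGA3 -1.24 (SE 0.19) and the ubiquitin-conjugating enzyme gene UBE2K -1.22 (SE 0.07). NEAT1 appeared longer, by 1.51 (SE 0.06), as did CPSF6 (0.48, SE 0.03), FBXO31 (0.38, SE 0.10), NPIPA9, which has close copies (0.38, SE 0.05), and SH3BP4 (0.36, SE 0.05), and NQO1 appeared shorter by a little (-0.19, SE 0.01). The averages of CPSF6 and SH3BP4 rest on the later times: CPSF6 had -0.05, 0.60 and 0.87 at 0, 3 and 6 h, and SH3BP4 had 0.01, 0.23 and 0.83. Of 13 measured genes known for 3′ UTR changes with cleavage factor Im 6 appeared shorter (median -0.13). Among 2322 genes with a mean count of at least 2000 there were 447 shorter and 100 longer, a ratio of 4.47.

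Apparent length rests on the authors' assignment of reads to annotated transcripts. A change of fragment size in whole libraries is argued against by genes with 1 annotated transcript, of which 0.6% (2 of 331) were called shorter, against 18.7% of 7879 genes with several, and by 23 spike-ins whose ratio had an SD of 0.003. Uneven coverage along transcripts could not be told apart from a change of ends: the median of genes with several transcripts was -0.013, which neither needs nor excludes it. Use of an earlier 3′ end may account for part of the shorter calls. Among genes with several transcripts, those whose annotated ends lie at least 500 nt apart were called shorter more often than the others (25.5% against 8.5%, odds ratio 3.68, Fisher's exact test p = 1.1e-86, across genes, which are not independent replicates). The distance is along the genome, introns included, and the number of transcripts was not adjusted for. The excess therefore does not tell an earlier end from uneven coverage. NUDT21, with 1 annotated end, is an exception. Of 100 splits of the libraries within each time 1, the real one, gave as many length calls (1711, highest other 343). This argues against chance, but a share of 1 in 100 is the smallest that 100 splits can give, so chance is not excluded.

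In the same 100 splits, 1, the real one, gave as many genes for the average over the times (9034), and the highest other gave 5603. This argues against chance here too, with the same limit. The other splits with over 1000 calls part the arms in 2 or 3 of the 3 times, some with the arms exchanged at a time, which points to the structure of the samples. Of the 100 splits 28 part all 6 same-numbered pairs as the real one does, and the highest values among the other 27 were 5603 genes and 343 length calls; the 72 that part fewer pairs reached 4808 and 28. The hypothesis that genes with a shorter apparent transcript lose RNA at another rate stays open. The length change and the difference of the 3 h change had a Spearman correlation of -0.044 with normalized counts and -0.033 with TPM across 8215 genes, and of -0.168 among the 1475 shorter calls, where genes are not independent replicates.

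Genes with the word AGAGAGA in the 3′ UTR (1974 of 10022) were lower in siCPSF6, by -0.107 (SE 0.013) at 0 h, -0.125 (SE 0.015) at 3 h and -0.132 (SE 0.016) at 6 h relative to other genes, after adjustment for length and GC content of the 3′ UTR. The word was the lowest of 16235 in rank score at 0 h (-9.1, where the highest absolute score in 20 runs on shuffled genes was 4.8). Of the 2224 lower calls at 0 h among these 10022 genes, 25.1% carried the word, against 19.7% of all 10022. These shares are not adjusted for length or GC content. The word's rank from the lowest was 2 at 3 h and 1 at 6 h. Base composition alone is argued against, as the lowest of 26 non-overlapping words of the same bases lay 7.9 higher in score. Overlapping words among the 35 of these bases were left out, so longer runs of alternating G and A were not tested. Pairing of the siRNA seed with 3′ UTRs could give such a shift (-0.107 at 0 h), but it cannot be told apart from other causes, since genes with the word in the coding part were also lower (-0.076, SE 0.011 at 0 h and -0.130, SE 0.015 at 6 h) and the siRNA sequences are not given in the sources used here. A role of CPSF6 itself at these genes, which the design would show in the same libraries, was not tested.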
